A study of Mus musculus with 2 samples.

How the data were processed

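Nuclei were isolated from frozen kidney cubes of 2 wild-type mice, 1 male and 1 female, by lysis and homogenisation with a last filtration through a 5 micron strainer, per the labels' protocols. The mice were Cre-negative animals carrying a floxed androgen receptor allele, per the series design text. Libraries were made with 10x Genomics droplet 3′ chemistry at a target of 20000 reads per nucleus. Reads were mapped to mm10 and counted with CellRanger 7.1.0, per the series design text, and the submitters' processing notes also name Seurat 5.1. How nuclei were filtered, how doublets were treated, how libraries were merged and how cell types were assigned is not given in the sources used here.

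The deposited table analysed here is text with 2 columns and 1 line per nucleus. One column holds a droplet barcode of 16 bases with a suffix of 1 or 2, and the other the cell type name that the authors gave that nucleus. No name was blank, and none marked doublets or unassigned nuclei. The number of columns of per-sample values left unused was 0. The table holds no UMI count, gene number or gene value per nucleus, so depth per nucleus is unknown here and the names could not be checked against marker genes. The markers and the named genes fixed before the data were examined, and the male against female gene values, were therefore not used.

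The suffixes were taken to separate 2 libraries. They match no title, description or other label of the 2 samples, and order was not used to assign them, so the libraries are described separately and not as male and female. The design fixed beforehand planned counts of nuclei per library only if a label tied barcodes to samples. No label did, so the counts depart from that plan, and counts and shares are given for each library without a group. Names were used as deposited after removing spaces at their ends. The 27 names were grouped into 13 classes from textbook anatomy after the names had been seen. "Glomerular" joins podocyte, mesangial and glomerular capillary endothelial names, "medullary collecting duct" joins the outer medullary principal and inner medullary names, and intercalated cells of all locations form 1 class.

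Shares were computed per library with exact Clopper-Pearson 95% intervals (scipy 1.17.1, pandas 2.3.3, python 3.11.15). Shares are said to differ beyond counting error when their intervals are separate, which describes these libraries and is not a test between animals or sexes. This rule is strict, so overlapping intervals do not show that 2 shares are equal. Nuclei are not replicates, and differences between tissue pieces, preparations and animals lie outside the intervals. The floor for a type with no nucleus was set at 3 counts of the library total. Ratios of types were compared between libraries as conditional odds ratios with exact intervals. In simulated independent binomial counts the lowest coverage of the intervals over 3 settings of 1000 draws each was 94.3%. These draws hold counting error only, so they check the computation and not spread between tissue pieces or animals. Alternatives were distinct barcodes, barcodes of a single library, a denominator without proximal tubule, leaving out types with under 20 nuclei in both libraries, and Wilson intervals. Counting proximal tubule segments 1 and 2 together was added after seeing the data. As a quality check, 3 barcodes occurred in both libraries, each with a different name in each. The planned probability of this overlap under independent draws is not given, so whether 3 is more than expected was not judged. No barcodes of 1 library differed by a single base. G and C made up 49.7% of barcode bases in both libraries, and single bases at single positions lay between 22.6% and 28.9%.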

Results

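Single nuclei were profiled from frozen kidney of 2 wild-type mice, 1 male and 1 female. The table analysed here assigns a cell type name, given by the authors, to each of 8564 nuclei. Nuclei fell into 2 libraries by the suffix of their droplet barcode. The library with suffix 1 (library 1) held 3044 nuclei and the library with suffix 2 (library 2) held 5520, where the protocol states a load of 5000 to 10000 nuclei per sample. Neither suffix matches a label of the male or the female sample, so no value below is tied to a sex and no comparison of the sexes was made. With 1 animal per sex there was also no replicate error, and no p-value is given. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. Among shares of all nuclei, the widest interval in library 1, that of the proximal tubule, reached 1.78 percentage points either side, and shares of smaller bases have wider ones. For a type with no nucleus a separate floor of 3 counts was used, which is 0.0986% of library 1 and 0.0543% of library 2. The upper bound of the exact interval is higher, at 0.121% for the 0 glomerular capillary endothelial nuclei of library 1.

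The first question was which parts of the nephron the nuclei represented. The 27 names were grouped into 13 classes. Over both libraries, proximal tubule, the segment that reabsorbs most of the filtrate and makes most renal ammonia, supplied 4575 nuclei, or 53.4% (52.4 to 54.5%). The thick ascending limb, which reabsorbs sodium chloride and ammonium, followed with 1502 nuclei, or 17.5% (16.7 to 18.4%). The distal convoluted tubule held 722 nuclei, or 8.43% (7.85 to 9.04%), and the connecting tubule 620, or 7.24% (6.70 to 7.81%). Medullary collecting duct and the endothelium of peritubular capillaries and vasa recta each held 294 nuclei, or 3.43% (3.06 to 3.84%). Intercalated cells, the acid-base transporting cells of the collecting system, held 219 nuclei, or 2.56% (2.23 to 2.91%). The remaining classes were rarer. Fibroblasts numbered 120, descending thin limb nuclei 90, glomerular nuclei 65 and macula densa nuclei 37. Smooth muscle and pericyte nuclei numbered 14, and macrophages, the only immune name in the table, numbered 12.

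The series title names NHE4, the sodium/hydrogen exchanger encoded by Slc9a4 (ENSMUSG00000026065.8), which is known from the basolateral membrane of the thick ascending limb. Slc9a4 lies on the plus strand of chromosome 1 from 40580081 to 40630725 in the GENCODE M21 annotation of the mouse build mm10. The table holds names and no gene values, so Slc9a4 expression was not analysed here. What it does give is the number of thick ascending limb nuclei. Thick ascending limb nuclei made up 21.1% of library 1 (641 nuclei, 19.6 to 22.6%) and 15.6% of library 2 (861 nuclei, 14.6 to 16.6%), with separate intervals. Almost all carried the cortical name. Cortical nuclei were 96.4% (94.7 to 97.7%) of the class in library 1 and 97.9% (96.7 to 98.8%) in library 2. Medullary thick ascending limb was represented by 23 nuclei in library 1 and 18 in library 2. Of nuclei outside the proximal tubule, the thick ascending limb held 38.7% (36.3 to 41.1%) in library 1 and 36.9% (35.0 to 38.9%) in library 2, and there the intervals overlapped.

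Proximal tubule nuclei were the one class with a higher share in library 2 beyond counting error. They made up 45.5% of library 1 (1386 nuclei, 43.8 to 47.3%) and 57.8% of library 2 (3189 nuclei, 56.5 to 59.1%). The segments along the proximal tubule did not share this difference equally. Segment 1, the early convoluted part, supplied 20 nuclei in library 1 and 353 in library 2. As a share of proximal tubule nuclei these were 1.44% (0.88 to 2.22%) and 11.1% (10.0 to 12.2%). Segment 2 held 42.3% (39.7 to 44.9%) of proximal tubule nuclei in library 1 and 47.2% (45.4 to 48.9%) in library 2. Segment 3, the straight part that reaches into the outer medulla, went the other way, with 56.3% (53.6 to 58.9%) in library 1 and 41.7% (40.0 to 43.5%) in library 2. As a share of all nuclei, segment 3 did not differ beyond counting error, at 25.6% (24.1 to 27.2%) and 24.1% (23.0 to 25.3%).

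**Figure D1:**
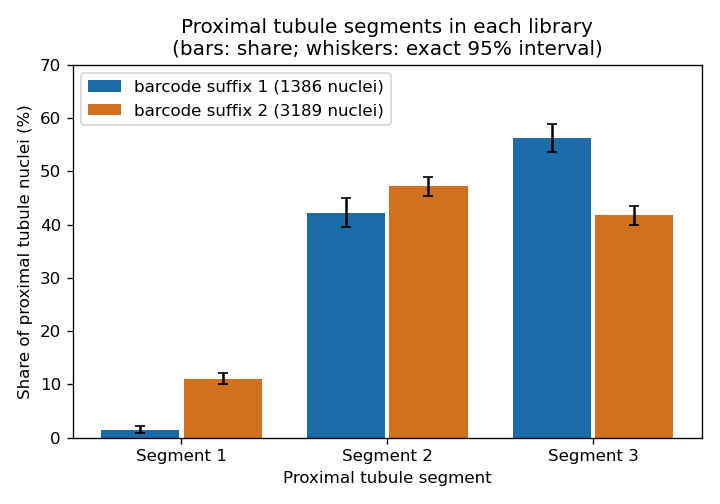
Share of proximal tubule nuclei (%) named segment 1, 2 or 3 in each library. Bars are shares and whiskers exact 95% intervals from counting error. Segment 1 stood at 1.44% in the library with barcode suffix 1 and 11.1% in that with suffix 2, and segment 3 at 56.3% and 41.7%.

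Another 5 classes had a higher share of all nuclei in library 1, with intervals separate from those of library 2. Besides the thick ascending limb these were glomerular, fibroblast, endothelial and medullary collecting duct nuclei. Glomerular nuclei made up 1.38% (0.996 to 1.86%) of library 1 and 0.417% (0.264 to 0.625%) of library 2. Podocytes, the filtration-barrier epithelium, numbered 29 and 14, which was 0.953% (0.639 to 1.37%) and 0.254% (0.139 to 0.425%). Fibroblasts made up 2.17% (1.68 to 2.75%) and 0.978% (0.736 to 1.27%), and the medullary fibroblasts among them numbered 24 and 6. Peritubular capillary and vasa recta endothelium held 4.86% (4.13 to 5.69%) and 2.64% (2.24 to 3.10%), and medullary collecting duct 4.24% (3.55 to 5.02%) and 2.99% (2.56 to 3.47%). The intervals of the other 7 classes overlapped. Among the 27 single names, 8 had separate intervals, 6 of them higher in library 1.

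Shares of a whole are bound to each other, so the larger proximal tubule share in library 2 leaves less for the other classes together. Not each of them was lower there. Shares were therefore also taken of nuclei outside the proximal tubule, an option listed before the data were examined. On this base, 4 of 12 classes had separate intervals. Distal convoluted tubule nuclei, the thiazide-sensitive segment, were then higher in library 2, at 20.8% (19.2 to 22.5%) against 14.3% (12.6 to 16.1%) in library 1. Glomerular nuclei stayed higher in library 1, at 2.53% (1.83 to 3.41%) against 0.987% (0.626 to 1.48%). Fibroblasts were at 3.98% (3.09 to 5.04%) in library 1 and 2.32% (1.74 to 3.01%) in library 2, and endothelium at 8.93% (7.60 to 10.4%) and 6.26% (5.31 to 7.32%). By single name, only medullary fibroblasts and ascending vasa recta endothelium had separate intervals within these classes. Intervals overlapped for the other fibroblasts, at 2.53% and 2.06%, for peritubular capillaries, at 5.07% and 4.25%, and for descending vasa recta, at 1.21% and 0.729%. Connecting tubule nuclei, at 14.4% (12.8 to 16.2%) and 16.3% (14.9 to 17.9%), and intercalated nuclei, at 5.25% (4.22 to 6.43%) and 5.66% (4.76 to 6.68%), did not differ beyond counting error. Medullary collecting duct, at 7.78% (6.54 to 9.18%) and 7.08% (6.07 to 8.20%), no longer did either.

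**Figure D2:**
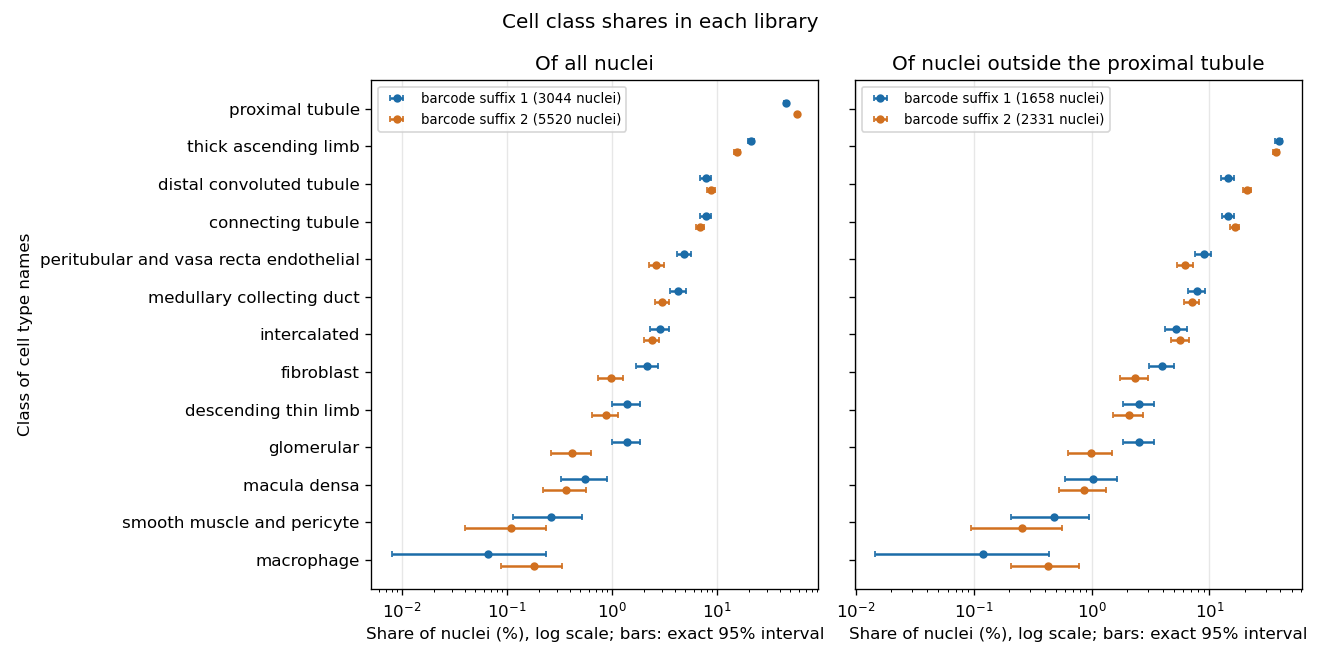
Share of nuclei (%, log scale) in each class of cell type names, of all nuclei on the left and of nuclei outside the proximal tubule on the right. Points are shares and bars exact 95% intervals from counting error, with 1 colour per library. Proximal tubule stood at 45.5% in the library with barcode suffix 1 and 57.8% in that with suffix 2, and outside it the thick ascending limb stood at 38.7% and 36.9%.

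Within the distal classes, the makeup of each class was compared next. Type 1 cells were 76.8% (70.9 to 82.0%) of distal convoluted tubule nuclei in library 1 and 80.6% (76.8 to 84.0%) in library 2. The connecting tubule principal name covered 20.1% (15.2 to 25.7%) and 16.8% (13.2 to 20.9%) of connecting tubule nuclei. Type B cells, the bicarbonate-secreting intercalated cells, were 47.1% (36.3 to 58.1%) and 59.1% (50.2 to 67.6%) of intercalated nuclei. None of these 3 pairs of intervals separated. The medullary collecting duct was the exception among the distal classes with more than 1 name. Its inner medullary nuclei were 89.1% (82.5 to 93.9%) of the class in library 1, with 115 inner and 14 outer medullary principal nuclei. In library 2 they were 71.5% (64.0 to 78.3%), with 118 and 47 nuclei.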

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

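With the proximal tubule left out of the denominator, the thick ascending limb stood at 38.7% in library 1 and 36.9% in library 2, connecting tubule at 14.4% and 16.3%, distal convoluted tubule at 14.3% and 20.8%, and medullary collecting duct at 7.78% and 7.08%. Endothelium stood at 8.93% and 6.26%, intercalated cells at 5.25% and 5.66%, fibroblasts at 3.98% and 2.32%, descending thin limb at 2.53% and 2.06%, glomerular nuclei at 2.53% and 0.987%, and macula densa at 1.03% and 0.858%. In library 2, macrophages stood at 0.429% and smooth muscle and pericytes at 0.257%. These shifts follow from the smaller denominator. Of the single names, 41 of the 48 shares left their interval for the same reason. Leaving out the 6 types with under 20 nuclei in both libraries (56 nuclei) moved the glomerular share to 0.961% and 0.255%, because only podocytes remain; macrophage and smooth muscle classes then had no value, and no single name's share moved. Proximal tubule segments 1 and 2 counted together, chosen after seeing the data, held 43.7% and 58.3% of proximal tubule nuclei, against 1.44% and 11.1% for segment 1 alone. Wilson intervals use the same counts, so they could change no share, and whether pairs of them separate was not examined. No line was repeated and no name was blank or marked doublets, so those settings could not change a value either. Dropping the 3 shared barcodes left the nuclei per library and the base composition within their limits. Matching reverse complements gave 0 shared barcodes and the first 15 bases gave 3. The male against female gene values were not run, since the table holds no gene values. No paired analysis was possible because the table ties no library to a group and no result comes from a test between groups.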

Other observations

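The tests of explanations and the ratios of types in this part were chosen after the shares had been seen, while shares of nuclei outside the proximal tubule were planned. The table's medullary and glomerular names had an uneven makeup that the class shares do not show. Over both libraries, inner medullary collecting duct nuclei outnumbered outer medullary principal nuclei by 3.82 to 1 (233 against 61), while cortical thick ascending limb nuclei outnumbered medullary ones by 35.6 to 1 (1461 against 41). By name, the thick ascending limb was thus almost wholly cortical in a table that also held 233 nuclei named inner medullary. It held 2111 nuclei of proximal tubule segment 3 as well, which reaches into the outer medulla. The names could not be checked against marker genes, so whether the thick ascending limb ratio reflects the tissue or the naming is not known. Inner medullary collecting duct held more nuclei than any other medullary name. No name covered the ascending thin limb, the cortical collecting duct principal cell, the glomerular parietal epithelium or any lymphocyte.

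Among glomerular cells, 43 nuclei were named podocyte, 20 mesangial and 2 glomerular capillary endothelial. Both glomerular endothelial nuclei were in library 2, and library 1 with 0 of 3044 nuclei allows a share of up to 0.0986% by the floor of 3 counts and 0.121% by the exact 95% interval. Podocyte shares of all nuclei had separate intervals between the libraries. Those of mesangial nuclei, 13 in library 1 and 7 in library 2, overlapped. The podocyte to mesangial ratio was 2.23 in library 1 and 2.00 in library 2, an odds ratio of 0.898 whose interval of 0.259 to 3.28 leaves open whether the names moved together. The inner to outer medullary collecting duct ratio went from 8.21 in library 1 to 2.51 in library 2, an odds ratio of 0.307 (95% interval 0.148 to 0.604, counting error only).

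The ratio of segment 1 to segment 2 proximal tubule nuclei was 0.0341 in library 1 and 0.235 in library 2, an odds ratio of 6.87 (4.33 to 11.5). One candidate explanation is a tissue piece with more cortex in library 2. Outside the proximal tubule, the 12 cortical names gained on the 8 medullary names by a smaller odds ratio, 1.46 (1.22 to 1.76). Segments 1 and 2 together gained on segment 3 by 1.80 (1.58 to 2.05), an overlapping interval. Of the nuclei with those cortical names, 618 of 1281 in library 1 and 843 of 1901 in library 2 were cortical thick ascending limb. Whether that name reflects the tissue or the naming is not known. Glomerular nuclei, which are cortical, went the other way and were lower in library 2. Medullary names with separate intervals were mixed. Of nuclei outside the proximal tubule, medullary fibroblasts were at 1.45% in library 1 and 0.257% in library 2, the direction of more cortex. Ascending vasa recta endothelium, at 2.65% and 1.29%, went that way too, while outer medullary principal nuclei, at 0.844% and 2.02%, did not. The names do not tell how far more cortex would move the ratio of segment 1 to segment 2. These values therefore cannot decide whether more cortex was the cause. A different line between the segment 1 and 2 names in the 2 libraries stays open as well. Segments 1 and 2 together against segment 3 also differed, but the line to segment 3 could have moved too, and deciding needs gene values per nucleus. Sex, the difference that the labels name, also stays open and untested, because the libraries are not tied to the animals. With 1 animal per sex, such a tie would still not separate sex from animal, tissue piece or preparation.

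Of the 19 types outside the proximal tubule with 20 or more nuclei over both libraries together, 5 had separate intervals for their share of nuclei outside the proximal tubule. Podocytes, ascending vasa recta endothelium and medullary fibroblasts were higher in library 1. Distal convoluted tubule type 1 and outer medullary principal nuclei were higher in library 2. These intervals hold counting error only, so ordinary spread between tissue pieces, preparations or animals was not measured, and no explanation of the larger proximal tubule share in library 2 was tested.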
